A study of Homo sapiens with 4 samples.

How the data were processed

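Gene expression was measured in HSC-3, an established human oral squamous cell carcinoma cell line that grows as an attached, epithelial-like layer. Per the labels' protocols, culture vessels were held in a 41 °C water bath, with 30 min of heating, and then returned to 37 °C for 0, 1 or 3 h, and untreated cells served as the control. Total RNA was treated with DNase, checked on a Bioanalyzer and labelled from the 3' end of the transcripts, per the labels' protocols. Each of the 4 conditions was hybridised to 1 Affymetrix Human Genome U133 Plus array. When the control cells were harvested, and whether they were handled in a bath without heating, is not given in the sources used here.

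The values used were the log2 probe set values deposited by the authors as 1 table for the 4 arrays, with 1 value per probe set and array. Per the submitters' processing notes the tool was RMA, which corrects background, quantile-normalises the arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here. The log base was not stated and was taken as 2 from RMA and from the range of the values, 1.60 to 14.3. The values were not centred per gene. Column medians were 4.44 in the control, 4.43 at 0 h, 4.41 at 1 h and 4.39 at 3 h, and after sorting no column lay further than 0.06 from the mean of the sorted columns. Normalisation of this kind assumes that the arrays share 1 distribution, so a change in total RNA per cell would not be seen.

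Probe sets were named from the platform annotation, with symbols matched by gene number to a RefSeq gene table of assembly GRCh38.p14 that was used for names and gene types only. Of the 54675 probe sets, 62 were control probe sets, 41097 had 1 gene symbol, 1801 had several and 11721 others had none. Control probe sets that carry a symbol were not set aside from the classes with symbols, so the classes overlap. They were not set aside from the choice of a gene's probe set either. Of the probe sets with 1 symbol, 41043 were matched through the gene number. Probe sets with several symbols named no gene. Other heat-inducible HSP70 genes than HSPA6 fell in that class, so their probe sets are reported as shared by more than 1 HSP70 gene, and no value is given for any 1 of those genes.

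A gene was represented by its probe set with the highest mean log2 value over the 4 arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. A gene entered a comparison if its value reached an expression floor in at least 1 of the 2 arrays. The floor was the median of all non-control probe set values, 4.42 on the log2 scale. Where the dimmer side lay below the floor, a fold against the floor is given as a lower bound, written as "at least". The floor is a working limit on dim signals, since detection calls were not used here.

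With 1 array per group there were no replicates, so no test was run and no p-value or standard error is given; the number of arrays limits the precision. Genes were counted at 2-fold, that is 1 on the log2 scale, for 5 comparisons: each heated array against control, 1 h against 0 h, and 3 h against 1 h. A robust SD of the log2 fold changes over genes is given as a description of how far apart a pair of arrays lay, real changes included. For 32 gene lists, the median log2 fold change was set against 10000 random lists of the same size matched on deciles of mean expression, and described by its percentile when at least 3 genes were above the floor. A list is called outside the middle 95% when it lay below the 2.5th or above the 97.5th percentile. Random lists do not carry the correlation between members of a real list, so the percentile describes these arrays only. The lists, the thresholds and the rule for named genes were fixed before the data were examined.

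The rule took, at each time against control, the 15 highest and the 10 lowest genes, and named those of them that changed at least 1.5-fold and whose median over all their probe sets had the same sign. It also named up to 4 members of each list with the largest change at any time, and the reference genes ACTB and GAPDH. Genes outside this rule are marked where they are named.

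The alternatives tried were thresholds of 1.5- and 3-fold, a floor at the 25th percentile (3.03 on the log2 scale), no floor, the mean of all probe sets of a gene, no probe sets with identifiers ending in _x_at or _s_at, a further cyclic loess normalisation, and counting probe sets 1 by 1. Overlaps between times share the control array, and were set beside 100 simulated sets of unchanged arrays. Their noise was drawn from the differences between the 0 h and control arrays only, real changes included. Apart from this, counts were tested on control values of 12669 genes with planted changes and independent normal noise, of SD 0.098 per array as in the pair of arrays that lay closest. Of genes changed 1.5-fold 2% passed 2-fold, of those changed 2.5-fold 96% and of those changed 4-fold 100%. With noise this small the simulation does not tell how many unchanged genes pass 2-fold. With the same noise, 10 of 200 lists of unchanged genes lay outside the middle 95%, and 200 of 200 lists shifted by 0.2 lay above it. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess.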

Results

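The series asked which genes of HSC-3 oral squamous carcinoma cells respond to mild hyperthermia. The data were 4 expression arrays, 1 each for untreated cells and for cells at 0, 1 and 3 h of recovery at 37 °C after 30 min at 41 °C. None of the groups was replicated, so every difference below is between 2 single arrays and has no replicate check. Between 27095 and 27455 of the 54675 probe sets reached the expression floor on each array. Correlations between arrays ran from 0.993 to 0.996 across probe sets, which are not independent replicates.

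A few heat shock genes, HSPA6 and DNAJB1 among them, stood far above control at the end of the heating and at 1 h, some inflammatory and immediate early genes were above control mainly at 1 h, and at 3 h fewer genes were 2-fold higher. At 0 h, 21 genes were at least 2-fold higher and 9 at least 2-fold lower than control, of 12819 above the floor. At 1 h the counts were 50 higher and 2 lower of 12809, and at 3 h they were 9 higher and 21 lower of 12888. The robust SD of log2 fold changes over genes was 0.14, 0.17 and 0.20 at the 3 times, so the arrays lay further from control as recovery went on while a 2-fold change stayed 7.23, 5.89 and 5.06 such SDs wide. The counts rest on the threshold: at 1.5-fold, 86 and 70 genes were higher and lower at 0 h, 190 and 99 at 1 h, and 172 and 146 at 3 h.

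The comparison of 0 h with control asked what had changed by the end of the heating. The highest gene was HSPA6, a strictly heat-inducible member of the HSP70 family, at 10.7 on the log2 scale against 3.95 in control. The measured ratio was 104-fold; since control lay below the floor, the bound was at least 75.6-fold, and the gene's 2 probe sets gave log2 fold changes of 5.08 and 6.70. DNAJB1, the HSP40 partner that stimulates the HSP70 ATPase, was 5.84-fold higher, DNAJB4 of the same family 2.65-fold, and ZFAND2A, a stress-inducible protein that binds the proteasome, 3.04-fold. HSPA1L, another HSP70 gene, was 6.45-fold higher by its brighter probe set, but its other probe set gave a log2 fold change of -0.05. The small heat shock proteins HSPB8 and HSPB1 had log2 fold changes of 1.01 and 0.89, and BAG3, a co-chaperone of HSP70, 0.98.

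Probe sets shared by more than 1 of the other heat-inducible HSP70 genes had a like course. The 3 probe sets of this kind were 2.71-, 5.63- and 3.14-fold above control at 0 h and 2.74-, 6.09- and 3.14-fold at 1 h. At 3 h they were at 1.71, 1.88 and 0.98 times the control level. Which of the genes they measured could not be resolved by the names.

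Of the 13 genes of the HSP70 and HSP110 list, 10 had a probe set of their own. The genes of the shared probe sets were not among them and are not counted. Of these 10, all above the floor, 2 were 2-fold higher at 0 h, HSPA6 and HSPA1L, the latter by 1 of its probe sets. The list median was 0.17, at the 99.97th percentile of random lists. Without probe sets ending in _x_at or _s_at that list lay at the 94.7th percentile. HSP40 proteins had 2 of 18 members 2-fold higher and a median of -0.0011 (36.2nd percentile), and the list of HSP90, HSP60 and small heat shock proteins had 1 of 10 and a median of 0.08 (96.4th percentile). Co-chaperones had none of 19 past 2-fold and a median of 0.06 (96.5th percentile). The constitutive chaperonin and prefoldin subunits had a median of 0.01 (59.3rd percentile). The heat shock factor list had 3 genes above the floor, HSF1 at 0.09, HSF4 and HSBP1, and a median of 0.09 (82.7th percentile).

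Beyond the chaperones, GCNA, a germ cell nuclear acidic protein, was 7.10-fold higher at 0 h, and TENT5A, a noncanonical poly(A) polymerase, 5.14-fold. One of the 3 probe sets of TENT5A gave 0.00. The noncoding RNA IDI2-AS1 was 3.07-fold higher, the pseudogene RPS16P5 2.60-fold, the G protein signalling regulator RGS2 2.46-fold and DEDD2, which carries a death effector domain, 2.32-fold. BMP4, a secreted growth factor, was at least 2.19-fold higher, and PRR19 at least 1.33-fold, since their control values lay below the floor.

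Part of the inflammatory and immediate early genes lay below control at 0 h. The chemokine gene CXCL2 had a log2 fold change of -1.46, IER3 -1.03, GADD45A, a stress gene and p53 target, -1.02, and TAF1D, a factor of RNA polymerase I transcription, -1.37. CXCL2 was measured by an _x_at probe set, and its other 2 probe sets lay below the floor. Of the NF-kB and inflammatory list, 15 of 21 genes were below control, 4 by at least 1.5-fold and 1 by 2-fold, and the median of -0.22 lay below all 10000 random lists. Without _x_at and _s_at probe sets, the median of the remaining 13 genes was -0.05 (10.0th percentile). The immediate early list had a median of -0.12, below all random lists, with 13 of 23 members below control and 10 above. KLF10 was at -0.95 and EGR1 at -0.41; FOS was at least 1.46-fold higher, its control value being below the floor, and IER5 was at 0.57, both named after the values were seen. With a lower floor that median was -0.03 (7.84th percentile).

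Other genes on the lower side at 0 h were NMRAL2P at -1.21 and PDLIM7 at -1.19, the latter with 7 probe sets that ran from -1.19 to 0.03. CCZ1B, ANKHD1, LRTM2 and ZNF350 lay below the floor after heating, which leaves bounds of at least 1.32-, 1.69-, 1.08- and 1.85-fold lower. The G2 and M phase list had 15 of 20 members below control and a median of -0.08 (percentile 0.01), with no member past 1.5-fold. Histones had a median of -0.07 (2.38th percentile), which was 0.02 without _x_at and _s_at probe sets.

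**Figure D1:**
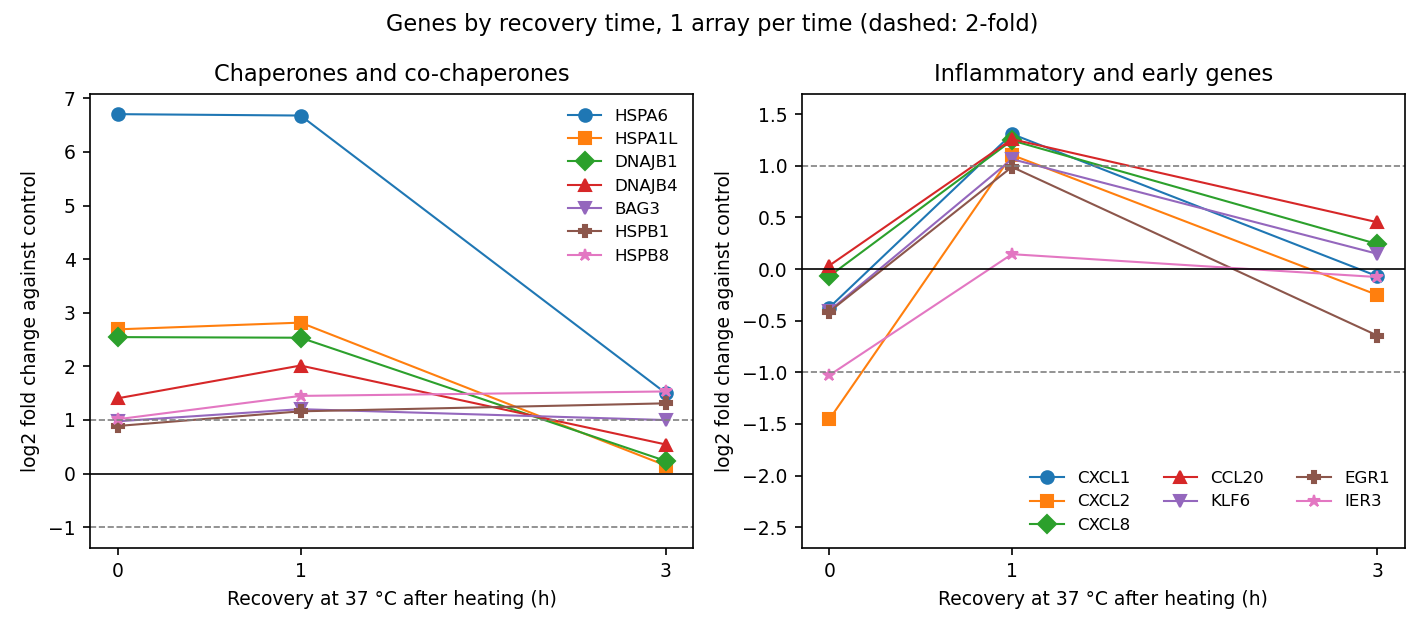
Log2 fold change against control (vertical axes) by hours of recovery at 37 °C (horizontal axes) for 7 chaperone and co-chaperone genes and 7 inflammatory and immediate early genes, 1 array per time; lines join the points and dashed lines mark 2-fold. DNAJB1 was at 2.55, 2.53 and 0.23, while CXCL2 was at -1.46, 1.11 and -0.25 by its _x_at probe set.

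The comparison of 1 h with control asked what the cells expressed early in recovery. HSPA6 was still 102-fold above control by the measured ratio (at least 74.3-fold), DNAJB1 5.79-fold, ZFAND2A 4.14-fold and DNAJB4 4.04-fold. HSPA1L was 7.04-fold higher by 1 probe set and at a log2 fold change of -0.72 by the other. HSPB8 was 2.73-fold higher, with its second probe set at 0.36, and HSPB1 and BAG3 were 2.24- and 2.30-fold higher. HSPA4L of the HSP110 group was at 1.19 and HSPH1 at 0.79.

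With the main choice of floor and probe sets, the medians of the chaperone lists were higher at 1 h than at 0 h. HSP70 and HSP110 had a median of 0.31 (above all random lists), with 3 of 10 genes 2-fold higher. Co-chaperones had a median of 0.14 (99.9th percentile), with CHORDC1 at 0.71 and STIP1, which links HSP70 to HSP90, at 0.54. HSP40 proteins had a median of 0.15 (99.9th percentile), but only 0.03 (70.6th percentile) with the mean of all probe sets. The median of the HSP90, HSP60 and small heat shock protein list was 0.14 (98.7th percentile), and under each of the 5 alternatives for lists it lay inside the middle 95%.

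With the main choice of probe sets, NF-kB and inflammatory genes formed the list furthest above control at 1 h. Of its 21 genes above the floor, 6 were at least 2-fold higher and 10 at least 1.5-fold, with none 1.5-fold lower, and the median of 0.52 lay above all random lists. The neutrophil chemokines CXCL1 and CXCL8 had log2 fold changes of 1.31 and 1.25, CXCL2 1.11, and CCL20, which attracts lymphocytes and dendritic cells, 1.26. CXCL2 was at -0.14 without _x_at and _s_at probe sets, but by a probe set below the floor in control and at 1 h. Without _x_at and _s_at probe sets the list median was 0.15 (99.0th percentile), below the 0.16 of apoptosis regulators in that setting.

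The lists of immediate early genes and of phosphatases that limit MAP kinase signalling had medians above random lists in the same array. The immediate early list had 20 of 22 genes above control, 5 of them by 1.5-fold and 1 by 2-fold, and a median of 0.29, above all random lists, with KLF6 at 1.06 and EGR1 at 0.99. MAP kinase phosphatases and feedback genes had 3 of 17 members 2-fold higher, 6 1.5-fold higher and 5 below control, and a median of 0.26, also above all random lists, with DUSP5 at 1.30, DUSP10 at 1.13, DUSP1 at 1.06 (-0.05 by a second probe set) and DUSP6 at 0.83. TGF-beta and YAP targets had a median of 0.25 (99.99th percentile), with CCN2 at 0.91 and AMOTL2 at 0.46 and 1 of 11 genes past 1.5-fold.

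The unfolded protein response of the endoplasmic reticulum had 17 of 21 members above control at 1 h, 4 of them by 1.5-fold and 2 by 2-fold, and a median of 0.32, above all random lists. DNAJB9, an HSP40 protein of that compartment, was 3.05-fold higher, with its 3 probe sets between 1.61 and 2.12 on the log2 scale. HERPUD1, a component of the degradation of misfolded endoplasmic reticulum proteins, was 2.75-fold higher, while DDIT3 and XBP1, transcription factors of the response, were at 0.97 and 0.46. Metallothioneins had all 7 members above control and a median of 0.15 (99.3rd percentile), led by MT1M at 0.83; most of their probe sets end in _x_at, a mark of probes shared with other transcripts.

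MMP3, the secreted protease stromelysin-1, was 3.71-fold above control at 1 h. BMP4 was at least 2.63-fold higher, the noncoding RNA LINC00622 2.67-fold and RSRP1 2.54-fold, the last with a second probe set at -0.36. The 2 genes at least 2-fold lower were TET1 and HOXB3. TET1, an enzyme that oxidises 5-methylcytosine, had a log2 fold change of -1.40 but lay below the floor after heating, which bounds it at 1.27-fold or more. HOXB3 was at -1.12, with a second probe set at -0.18, and CYP1B1, a cytochrome P450 enzyme, was 1.99-fold lower, with 3 probe sets above the floor between -1.06 and -0.99. DLX1 at -0.89, with a second probe set at 0.22, and ZFP69 at -0.92 followed, and CDKN2D, CTSW, HOXA-AS2, DNAJB13 and PIP5KL1 lay below the floor, with bounds between 1.20- and 1.93-fold.

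**Figure D2:**
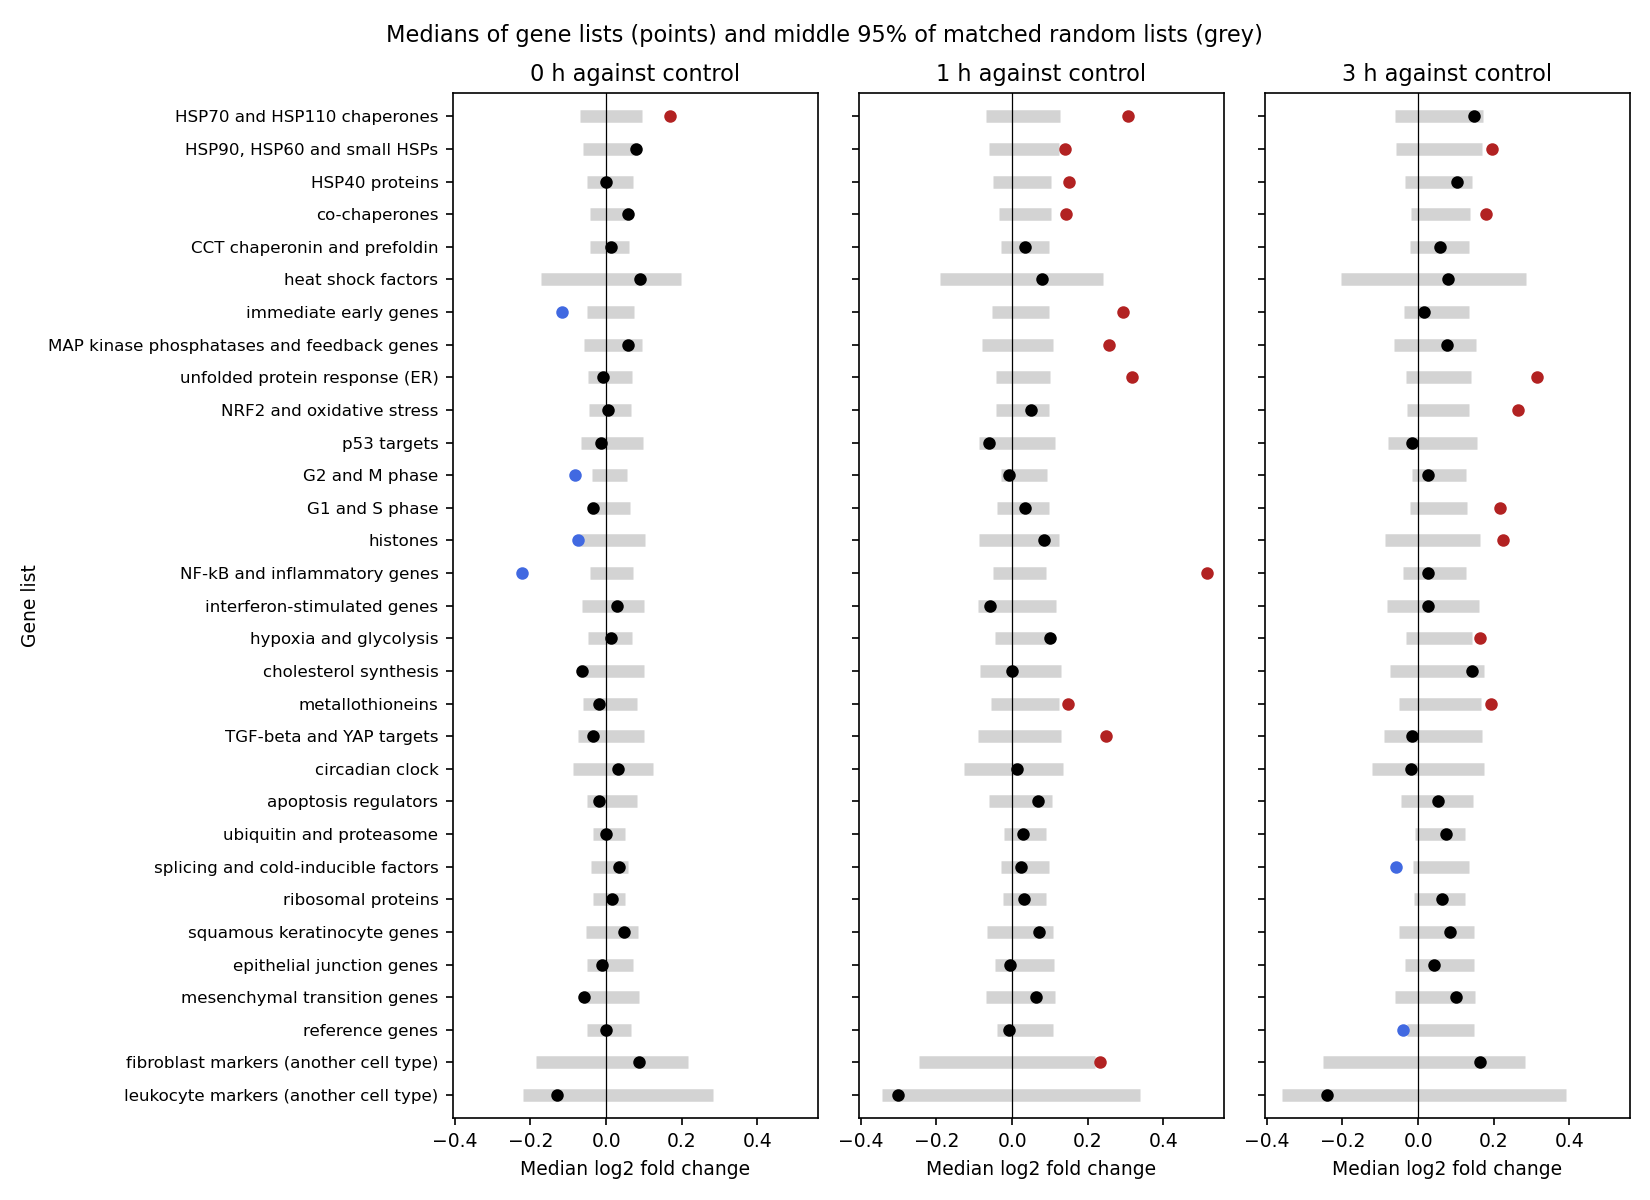
Median log2 fold change (horizontal axes) of 31 gene lists at 0, 1 and 3 h against control, as points, red above and blue below the middle 95% of 10000 matched random lists (grey bars), black within it. The median of the NF-kB and inflammatory list was at -0.22, 0.52 and 0.03 in the 3 panels.

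The comparison of 3 h with control asked which differences lasted. MMP3 was 3.30-fold above control, HSPB8 2.89-fold by its brighter probe set (the other gave -0.12), HSPB1 2.48-fold and ZFAND2A 2.10-fold. HSPA6 was 2.82-fold higher by the measured ratio and at least 2.05-fold against the floor. BAG3 was 2.00-fold higher, whereas HSPA1L, DNAJB1 and DNAJB4 had log2 fold changes of 0.15, 0.23 and 0.54. FOLR1, a folate receptor, was 2.75-fold higher, the pseudogene UBBP1 2.04-fold, the transcription factor gene KLF11 1.99-fold (its second probe set, below the floor, gave -0.09) and MT1M 1.99-fold. SLC22A12 and ARHGAP27P1 had control values below the floor, with bounds of at least 1.11- and 1.13-fold. The second probe set of ARHGAP27P1, below the floor, gave -0.08.

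Several stress lists lay above random lists at 3 h through small differences of many members. The same array also differed from control in 18S ribosomal RNA, at -1.22, and in the poly-A spike-ins, at -0.22 ± 0.22 (mean ± SD over probe sets). With 1 array per time the small shifts of the lists were not separated from differences in RNA or labelling. The poly-A spike-ins were also at -0.17 ± 0.19 at 1 h, so small list shifts at 1 h have this limit too. The unfolded protein response had 18 of 21 members above control and a median of 0.31, above all random lists, with XBP1 at 0.65. The NRF2 and oxidative stress list had 15 of 16 and a median of 0.26, also above all random lists, with HMOX1, which breaks down haem, at 0.96, GCLM of glutathione synthesis at 0.70 and SLC7A11, the cystine transporter, at 0.51. Co-chaperones had 18 of 19 and a median of 0.18 (99.7th percentile), with STIP1 at 0.63. Metallothioneins had a median of 0.19 (99.0th percentile). The HSP70 and HSP110 median of 0.15 lay at the 94.8th percentile, and at the 99.8th with the mean of all probe sets. The HSP90, HSP60 and small heat shock protein median of 0.19 lay at the 98.9th percentile, and at the 77.6th without _x_at and _s_at probe sets.

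Cell cycle genes of the G1 and S phases had 16 of 20 members above control at 3 h and a median of 0.22, above all random lists, with CDC6 at 0.52, CDT1 at 0.47 (-0.32 by its second probe set) and MCM2 at 0.28; E2F1 was at -0.40. With the mean of all probe sets the median was 0.09 (82.4th percentile). Histones had a median of 0.22 (99.8th percentile), with H2BC9 at 0.61 and H2BC5 at 0.46. The median of hypoxia and glycolysis genes was 0.16 (99.2nd percentile), and 0.09 (85.1st percentile) with the mean of all probe sets. The NF-kB and inflammatory list at 0.03, the immediate early list at 0.01 and the MAP kinase feedback list at 0.08 lay inside the middle 95%.

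Genes lower at 3 h included several noncoding RNAs. LOC114224 had a log2 fold change of -1.46, MIR181A2HG, the host transcript of a microRNA, -1.31, FUT8-AS1 -1.21 and FTX -1.13, the last with a second probe set, below the floor, at 0.11. LRRC69 was at -1.39, CYP1B1 at -1.24 with 3 probe sets above the floor between -1.25 and -1.20, and the pseudogene BMS1P2 at -1.14. ZBTB37, CTSW and NAIP lay below the floor after heating, with bounds of at least 2.25-, 1.57- and 1.39-fold lower. The median of splicing factors, splicing kinases and cold-inducible RNA-binding proteins was -0.06 (percentile 0.14), with SRSF5 at -0.66 and the kinases CLK1 at -0.12 and CLK3 at 0.69; without _x_at and _s_at probe sets it was 0.00 (25.8th percentile). In the same array the 3 probe sets of 18S ribosomal RNA were -1.22 ± 0.51 from control (mean ± SD over probe sets), against -0.20 at 1 h.

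Probe sets without a gene symbol held most of the 2-fold lower signals at 3 h. Of 3481 such probe sets above the floor, 224 (6.43%) were at least 2-fold lower than control, against 101 (0.43%) of 23747 with 1 symbol. They made up 224 of the 329 probe sets of any kind that were 2-fold lower. At 0 h the numbers were 23 of 3493 (0.66%) and 44 (0.19%), and at 1 h 4 of 3477 (0.12%) and 8 (0.03%).

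**Figure D3:**
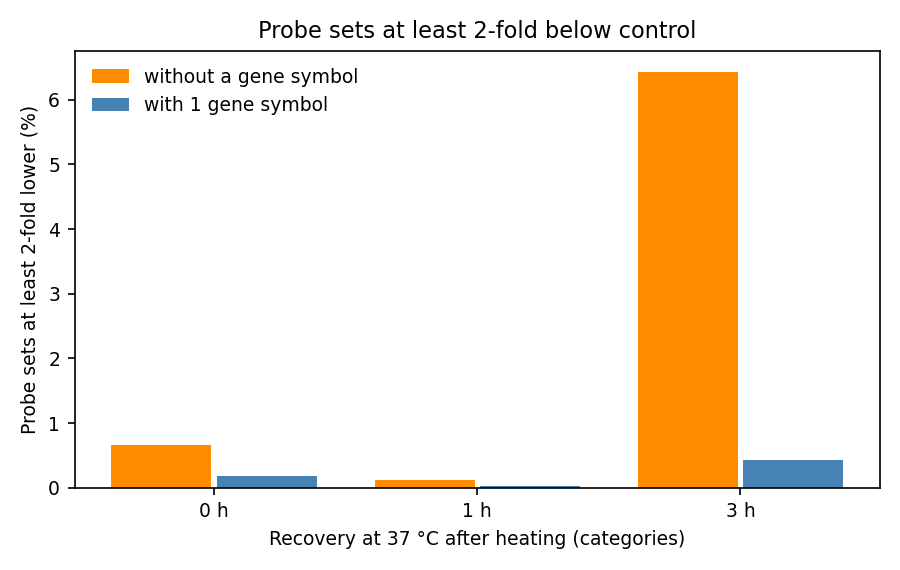
Percent of probe sets above the floor that were at least 2-fold below control (vertical axis) at 0, 1 and 3 h of recovery (horizontal axis), for probe sets without a gene symbol and with 1 symbol. The bars at 3 h stand at 6.43% and 0.43%.

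The comparison of 1 h with 0 h asked what differed within the early recovery. At least 2-fold higher at 1 h than at 0 h were 40 genes, with 5 lower, of 12866. The NF-kB and inflammatory list supplied 11 of them and had a median of 1.22, above all random lists. Without _x_at and _s_at probe sets its median was 0.45 over 12 members. The 11 members not measured by such probe sets in the main results had a median of 0.66. CXCL2 and CXCL8, both measured by _x_at probe sets, were at 2.56 and 1.32, CXCL1 at 1.68 and CCL20 at 1.22. Immediate early genes had 5 of 23 members 2-fold higher and a median of 0.41, above all random lists, with KLF6 at 1.47, EGR1 at 1.40, KLF10 at 1.23 and IER3 at 1.17. DDIT3 was at 1.58 and DNAJB9 at 1.24. Among heat shock genes HSPA6 was at -0.03, DNAJB1 at -0.01, DNAJB4 at 0.61 and HSPA4L at 0.69, while TENT5A was lower at -1.12.

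Between 1 h and 3 h the direction turned. Only 14 genes were at least 2-fold higher at 3 h than at 1 h and 44 were lower, of 12870. HSPA6 had a log2 difference of -5.18, HSPA1L -2.67 (0.49 by its second probe set), DNAJB1 -2.30 and DNAJB4 -1.47. HSPB1, HSPB8 and BAG3 were at 0.15, 0.08 and -0.20, with the second probe set of HSPB8 at -0.47. The NF-kB and inflammatory list had 6 of 21 members 2-fold lower and a median of -0.48, below all random lists. Among its members CXCL1 was at -1.38, CXCL2 at -1.36 and CCL20 at -0.80. Without _x_at and _s_at probe sets its median was -0.23 over 12 members. The immediate early and MAP kinase feedback lists had medians of -0.27 and -0.25, both below all random lists. The HSP70 and HSP110 list had a median of -0.21 (percentile 0.01), and the NRF2 list a median of 0.17, above all random lists.

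Set side by side, 62 genes were at least 2-fold above control at some time, and 9 of these were so at 3 h. The highest value fell at 0 h for 16 genes, at 1 h for 40 and at 3 h for 6. This split rests on the threshold: at 1.5-fold it was 66, 150 and 147 of 363 genes, of which 173 were past the threshold at 3 h among the 13089 genes above the floor on any of the 4 arrays, and at 3-fold 5, 5 and 0 of 10. The sets at 0 and 1 h shared 13 higher genes out of 21 and 50, against 0.08 for independent lists and a mean of 4.32 in simulated unchanged arrays with a shared control. At 0 and 3 h 3 genes were shared (simulated mean 4.21), and at 1 and 3 h 5 (4.30). At 1.5-fold the shared higher genes were 41, 17 and 45 for the 3 pairs of times, against simulated means of 23.45, 23.05 and 23.07. Shared genes 2-fold lower were 0, 1 and 0, against 4.67, 4.58 and 4.60. Those 1.5-fold lower were 9, 12 and 22, against 23.5, 23.36 and 23.37. Only 2 genes were 2-fold lower at 1 h, so overlaps with that time could not have reached the simulated means. The simulation gave its noise random signs, and it did not keep the number of genes past the threshold at each time. Its noise came from 0 h against control only, where the robust SD over genes was 0.14, against 0.17 at 1 h and 0.20 at 3 h. Neither a shortfall of shared lower genes nor an excess of shared higher genes is therefore read from the simulation. The simulated noise included real changes between arrays, and part of each overlap may come from the single shared control, which could not be split.

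Most groups outside the stress responses lay within the middle 95% of random lists at all 3 times against control. These were p53 targets, interferon-stimulated, cholesterol synthesis, circadian clock, apoptosis, ubiquitin and proteasome, ribosomal protein, squamous keratinocyte, epithelial junction and mesenchymal transition genes. The choice of floor and probe sets mattered for 2 of them: mesenchymal transition genes lay at the 99.4th percentile at 1 h and the 98.1st at 3 h with a lower floor, and apoptosis genes at the 98.6th at 1 h without _x_at and _s_at probe sets. Single members differed more: BHLHE40 of the clock list was at -0.79 at 0 h and 0.78 at 1 h (0.00 by its second probe set), PMAIP1 of the apoptosis list at 0.61 at 1 h, and SNAI2, a repressor of epithelial genes, at -0.57 and 0.52. The reference genes ACTB and GAPDH were at 0.15 and -0.01 at 0 h, 0.19 and 0.04 at 1 h, and 0.10 and 0.15 at 3 h. The reference list median of -0.04 at 3 h lay at percentile 1.62, and at percentile 3.50 without _x_at and _s_at probe sets.

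Markers of other cell types gave no common shift. Leukocyte markers, with 3 or 4 of 10 genes above the floor, had medians of -0.13, -0.30 and -0.24 at the 9.66th, 4.47th and 8.74th percentiles; with a lower floor the 1 h median lay at the 1.265th. Fibroblast markers, with 4 or 5 genes above the floor, had medians of 0.09, 0.23 and 0.16, of which that at 1 h lay at the 98.0th percentile and at the 80.7th with a lower floor; COL1A1 was at 0.38 at 1 h. Endothelial markers had 2 genes above the floor, too few for a percentile. Of the 31 lists with a percentile, 1 lay above and 4 below the middle 95% at 0 h, 11 and 0 at 1 h, and 8 and 2 at 3 h. With random lists 0.78 would lie on each side. Random lists do not carry the correlation between members of a real list, so these counts are no test against chance.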

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

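All tests in this part were chosen after the results were seen. For 17 genes the differences from control pointed in opposite directions, with at least 1.5-fold above control at 1 time and at least 1.5-fold below it at another. With 1 array per time these differences were not tested, and every gene rests on the same control array. Of the 17 genes, 5 were lower at 0 h and higher at 1 h: the log2 difference between 1 h and 0 h was 2.56 for CXCL2, 1.62 for TNFAIP3, an inhibitor of NF-kB signalling, 1.58 for DDIT3, 1.58 for BHLHE40 and 1.55 for DUSP6. CXCL2 was measured by an _x_at probe set, and the second probe set of BHLHE40 did not share its rise at 1 h. ADAMTS1 was lower at 0 h and higher at 3 h, by 1.36 between them.

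The 8 genes that were lower at 3 h and higher earlier included EGR1 and NFKBIZ, which lay 1.63 and 1.65 higher at 1 h than at 3 h on the log2 scale, and RUNX1-IT1, 1.76 higher. For the other members the highest value was at 0 h, by 2.39 for RPS16P5, 2.04 for EIF3C, 1.64 for PPP1R10, 1.56 for XNDC1N and 1.39 for LRIG2. Lower at 1 h and higher at 3 h were DLX1, BCL11A and S1PR5, by 1.495, 1.44 and 1.38. The second probe set of DLX1 was at 0.22 at 1 h. The 3 h array, on which the 8 genes were lower, also differed from control in 18S ribosomal RNA, at -1.22.

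Probe sets that named no single gene, and so entered none of the gene counts, also held signals above control. At least 2-fold higher were 26 of them at 0 h, 14 at 1 h and 10 at 3 h. The shared HSP70 probe sets were among those at 0 and 1 h. Of probe sets with several symbols, 7 were higher and 3 lower of 1136 at 0 h, 5 and 1 of 1125 at 1 h, and 1 and 4 of 1133 at 3 h. Of those without a symbol, 19 were higher and 23 lower of 3493, 9 and 4 of 3477, and 9 and 224 of 3481.

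The 2-fold lower signals at 3 h were concentrated in probe sets without a gene symbol. The count of 224 argues against error as large as in named probe sets of the same mean level. For those, 1000 draws gave 23.5 on average and 42 at most. The draws matched mean level only, so they cannot tell whether probe sets without a symbol have larger error at the same level. At 0 h such probe sets went both ways, with 19 higher and 23 lower against a highest draw of 19 for lower ones. Counts were 9 higher and 4 lower (highest draw 9) at 1 h, and 9 higher and 224 lower at 3 h. Among named genes, 10 of 688 long noncoding RNA genes were 2-fold lower, against at most 7 in matched draws of protein-coding genes. Less RNA without a poly-A tail in the labelling of the 3 h array may account for this concentration. The 18S ribosomal RNA probe sets were at -1.22 at 3 h and -0.20 at 1 h. Recovery time and array cannot be told apart with 1 array per time. Loss of 5' ends stays open as well: the 5' minus 3' difference against control was 0.24 for GAPDH and -0.50 for ACTB at 3 h, where spike-ins ran from -0.34 to 0.30, and -0.04 and -0.35 at 1 h, where only 4 probe sets were lower. An effect of the heating on such transcripts would have to be late, given the few lower at 1 h, and it was not tested.

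Of the 21 NF-kB and inflammatory genes above the floor, 15 were below control at 0 h, 4 of them by 1.5-fold, and 16 above it at 1 h, 10 of them by 1.5-fold. An error of the single 0 h array was not tested and stays open. Signal from probe sets ending in _x_at or _s_at is a candidate explanation of the lower values at 0 h that stays open: without them the percentile was 10.0 at 0 h and 99.0 at 1 h. The 11 members measured by other probe sets went both ways at 0 h, with 6 below control, such as IL6 at -0.94 and CXCL3 at -0.40, and others above it, such as IL24 at 0.24. A brief drop of short-lived transcripts during heating, followed by renewed expression, stays open as a hypothesis; no decay rates were analysed here.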

How the results depend on the processing

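All alternatives in this part were planned. The fold threshold moved every count: in the order 0 h, 1 h and 3 h against control, 1 h against 0 h and 3 h against 1 h, a threshold of 1.5-fold gave 86, 190, 172, 153 and 115 genes higher and 70, 99, 146, 94 and 169 lower. A threshold of 3-fold gave 7, 7, 1, 5 and 0 higher and 0, 0, 0, 1 and 10 lower. Probe sets counted 1 by 1 gave 65, 92, 29, 108 and 37 higher and 70, 13, 329, 47 and 339 lower. With the mean of all probe sets of a gene, 30 genes were 2-fold higher and 0 lower at 1 h, 10 lower at 3 h, 3 lower at 1 h against 0 h, and 6 higher and 27 lower at 3 h against 1 h. Without _x_at and _s_at probe sets, 4 were lower at 1 h and 9 at 1 h against 0 h. All other counts of these 5 comparisons at 2-fold lay within 1.5 times the main count with the lower floor, no floor, the mean, no such probe sets, or loess. Of the genes 2-fold higher at any time, 24 were highest at 1 h with the mean of probe sets, and 3 were highest at 3 h without _x_at and _s_at probe sets. The thresholds and the counting unit move these counts by construction; for the others the cause was not tested.

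Under the lower floor, no floor and cyclic loess, all 420 values of named genes stayed within 1 robust SD. With the mean of probe sets 318 did, and 102 moved further, with no called value reversed; without _x_at and _s_at probe sets 262 of 309 did. In that setting CXCL2 at 1 h was at -0.14, ARHGAP27P1 at 3 h at -0.079 and HSPB8 at 3 h at -0.12, the histone median at 0 h was 0.024 and the splicing list median at 3 h was 0.0045, all with the opposite sign. The CXCL2 and ARHGAP27P1 values came from probe sets below the floor and so do not show a reversal. Of 26 list medians outside the middle 95%, 22 stayed there on the same side with the lower floor, 21 with no floor, 21 with the mean of probe sets and 25 with loess, and 16 of 23 without _x_at and _s_at probe sets. In the same order 3, 2, 8, 2 and 3 further list medians moved outside it. Dim signals limit the rest: where 1 side lay below the floor, a fold is only a bound.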

Other observations

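The genes in the next 2 paragraphs were chosen after their values were seen. They are single genes at least 2-fold above control at 1 h, or at 0 h, that the naming rule left out, and they were not tested as a group. HBEGF, a ligand of the EGF receptor, was at a log2 fold change of 1.19 at 1 h and -0.49 at 0 h, EDN1, the precursor of a vasoactive peptide, at 1.19 and -0.21, and IL11, a cytokine of the IL-6 family, at 1.21 and 0.40. SOCS3, which limits cytokine signalling, was at 1.15 at 1 h, PRDM1, a transcriptional repressor, at 1.16, and the zinc exporter SLC30A1 at 1.07. All but IL11, at 0.78, lay between -0.30 and 0.20 at 3 h. Other probe sets above the floor gave -0.31 at the lowest for EDN1 at 1 h, -0.28 for PRDM1, and 0.13 for IL11. EIF2AK3, a kinase that senses unfolded protein in the endoplasmic reticulum, was at 1.04 at 1 h and 0.33 at 3 h. Its second probe set, below the floor, was at -0.39 and -0.33.

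Among developmental regulators, 5 single genes had values above control at each time. GAS1 was at 1.23, 1.04 and 0.76 at 0, 1 and 3 h by its only probe set above the floor, with a median over its 3 probe sets of -0.22 at 0 h, and the transcription factor genes OSR2 at 1.05, 1.04 and 0.76, EN2 at 1.01, 0.97 and 0.46, MSX1 at 0.93, 1.01 and 0.36, and TBX3 at 1.03, 0.69 and 0.12. At 1 h the second probe set of MSX1 was at -0.08, and 4 of the 7 probe sets of TBX3 lay above the floor, between -0.13 and 1.13. Other regulators were lower, such as HOXB3 at -1.12 and DLX1 at -0.89 at 1 h. Over 151 genes of developmental transcription factor families, of which 89 were above the floor at 3 h, the median was 0.06 at 0 h (95.1st percentile of random lists) and 0.01 at 1 h (61.7th), both inside the middle 95%, and 0.14 at 3 h (99.96th), outside it. At 0, 1 and 3 h, 4, 6 and 7 of them were at least 1.5-fold higher and 1, 3 and 1 lower. These families were picked after the values were seen, and they do not hold all of the 5 genes named first. The percentile at 3 h is therefore no independent check on those 5 genes. The 3 h array also differed from control in 18S ribosomal RNA, at -1.22.

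Spike-in control probe sets were also compared between each heated array and the control array. Their SDs are over probe sets of 1 pair of arrays and do not measure spread between replicate arrays. The 9 hybridisation controls differed from the control array by 0.09 ± 0.05 at 0 h, 0.02 ± 0.08 at 1 h and -0.02 ± 0.09 at 3 h (mean ± SD over probe sets, log2). The 12 poly-A controls differed by 0.05 ± 0.18, -0.17 ± 0.19 and -0.22 ± 0.22.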
